A study of Arabidopsis thaliana with 12 samples.

How the data were processed

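RNA was taken with an RNeasy column kit from roots of 8-day-old dark-grown seedlings of 4 genotypes (Col, LBD29-OE, MYB2-OE and MYB2-SRDX), 3 samples each, and random-primed cDNA libraries were sequenced on an Illumina instrument, per the labels' protocols. Groups came from the genotype labels. Nothing in the labels says whether the 3 samples of a genotype were separate cultures. A p-value from a test across samples therefore measures only the spread between these samples, which may be technical. Tests that count genes do not measure that spread. The columns of the MYB2-SRDX table carry a name that differs from the sample titles, so they were assigned to that group without replicate numbers, and its libraries are named by the digit their column ends in.

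The authors deposited 3 tables, each Col against 1 line, with FPKM per library and a mean FPKM per group, per the file headers. These tables also held the authors' log2 fold change and the authors' p-value and Q-value (an adjusted p-value) per gene, per the file headers, and both MYB2 tables repeated the log2 fold change and Q-value of LBD29-OE. Per the submitters' processing notes the genome build was TAIR10. The aligner, the counting tool, the handling of multiply mapped or overlapping reads and the test behind the authors' p-values are not given in the sources used here. The authors called CAB2 in LBD29-OE with libraries at 0, 36.4 and 0.550 FPKM, so a small Q need not reflect all 3 libraries. Checked on the values, every listed gene had an absolute log2 fold change above 1, the largest Q was 0.000999, the group means equalled the means of the library FPKM, and Col values of genes shared by 2 tables were identical (largest difference 0). The authors' log2 lay within 0.1 of the log2 ratio of mean FPKM for 96.2, 96.6 and 95.3% of the genes listed for LBD29-OE, MYB2-OE and MYB2-SRDX. Since only called genes were listed, a gene outside a table can be unchanged, undetected or under the authors' thresholds.

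Depth per library was looked for in the steps of low FPKM values. At equal depths, 23.1 to 62.5% of the usable genes of a library (8 to 37 genes) came out at whole reads within a tolerance of 0.1 reads, where chance gives 20%, so the depth is unknown and no test on reads was run. No interval or floor that needs depth is given. FPKM below 1 occurred as the higher group mean of 231, 296 and 274 listed genes in LBD29-OE, MYB2-OE and MYB2-SRDX, and their folds are the least certain.

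Before the data were examined, the groups, the comparisons, 18 gene lists with 255 genes, the rule for named genes and the alternatives were fixed, with a separate course for filtered tables. The tables turned out to be filtered, so the authors' calls (Q under 0.05 and absolute log2 of at least 1) were counted as the result of each comparison, and no test across genes was the main result. Named genes were LBD29 and MYB2, the 8 largest rises and the 8 largest falls with a symbol and a higher group mean of at least 10 FPKM, up to 4 listed members per gene list, and up to 5 genes per direction class of each overlap. The lists covered lateral root and callus genes, cell separation, auxin, abscisic acid and dehydration, hypoxia, cytokinin, phosphate starvation, iron deficiency, nitrate, xylem, root hair, endodermis and suberin, green tissue, seed storage, cell cycle, defence and camalexin, jasmonate, and flavonoid synthesis. Higher against lower members of a list were compared with the share of higher calls in the table by a two-sided exact binomial test with Benjamini-Hochberg adjustment. A list of 11 dawn-phased clock genes was made after falls of some of its members had been seen. A list of 10 dusk-phased clock genes was made at the same time, before values of its own members had been seen. The clock genes named outside the rule were chosen after their values were seen.

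Shared genes of 2 tables were counted by direction, with exact binomial 95% intervals. These intervals and the tests on shared genes take genes as independent, which genes measured in the same libraries are not. The two-sided Fisher's exact tests on the direction classes were added after the tables were seen, and the test of overlap size fixed earlier is not given, because the set of genes the authors tested is unknown. Chance from the shared Col libraries was simulated with 100 draws of unchanged lines from the Col spread of the genes in either table, without the authors' selection. As alternatives, folds were recomputed from mean FPKM with a pseudocount of 1 or 0.1, and limma was run on log2(FPKM + 1) of the listed genes with a Benjamini-Hochberg threshold of 0.05. A fold on the log2(FPKM + pseudocount) scale understates changes of low genes, and a limma test on listed genes starts from genes the authors had already selected. In simulated data with 200 changed genes, limma recovered 98, 99 and 96% of changes of log2 1.5 and 100, 99 and 99% of changes of log2 2.5 among 802, 1271 and 1045 genes for LBD29-OE, MYB2-OE and MYB2-SRDX, with 1, 1 and 0 false calls. Both simulated groups had the spread of the Col libraries. Real libraries of the lines correlated less, at 0.802 to 0.892 in MYB2-SRDX against 0.963 to 0.970 in Col, so these rates may not hold for them. With 3 against 3 libraries an exact permutation test of a gene cannot go below p = 0.1, so none is given per gene.

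A library was taken to stand apart when more than 10 listed genes lay over 4-fold above both other libraries of its group, a rule chosen after the data were seen. This held for LBD29-OE replicate 2 (26 genes), MYB2-OE replicate 2 (21 genes) and MYB2-SRDX library 1 (117 genes). Results without them were computed with the pseudocount of 0.1. The gene ontology terms given by the authors' deposited tables were compared between higher and lower genes of a table by Fisher's exact test, also chosen after the data were seen, and transcription factor families were counted without a test.

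The reference annotation TAIR10.1 served for symbols and for neighbouring genes, and no coordinates are printed because the authors' build carries another name. It lacked 2, 12 and 3 of the genes listed for LBD29-OE, MYB2-OE and MYB2-SRDX, which have organelle identifiers. Reads of near-identical copies can be split between genes, so values of AIR1, the IGMT genes, GSTF2 and GSTF3, GSTF6, the RBCS genes and CAB2 are uncertain. The same holds for genes that overlap an annotated neighbour, among them PGLR, CDEF1, AIR1, MES17, PUP7, MYB24, ACA1, SP1L2, NAC042, HSP17.4, LNK2, LNK1, LNK4, RVE1, RAB18, PAP17 and JAZ10, since use of strand is not given in the sources used here. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.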

Results

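Transcripts of Arabidopsis thaliana roots were measured by RNA sequencing in 4 genotypes, with 3 libraries per genotype and 12 libraries in all. The roots came from 8-day-old seedlings raised in darkness. Col is the wild type. LBD29-OE overexpresses LBD29 (AT3G58190), a LATERAL ORGAN BOUNDARIES DOMAIN transcription factor that acts in lateral root formation. MYB2-OE overexpresses MYB2 (AT2G47190), a MYB transcription factor known from abscisic acid and drought responses. MYB2-SRDX expresses MYB2 fused to SRDX, a short plant repression domain, and is labelled a dominant negative line. The labels give the viral 35S promoter for the transgenes. Each transgenic line was set against Col in a deposited table that listed only genes the authors called, with FPKM per library, so a gene outside a table has no value for that comparison. Sequencing depth per library is unknown, because FPKM values do not carry it. The tables held 2424 different genes, of which 1845 stood in 1 table, 464 in 2 and 115 in all 3.

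The transgenes were read first, as a check on the labels. LBD29 measured 2.89 ± 0.295 FPKM in Col and 546 ± 63.8 FPKM in LBD29-OE (SD, n = 3). MYB2 measured 0.693 ± 0.280 FPKM in Col, 532 ± 138 FPKM in MYB2-OE and 505 ± 52.0 FPKM in MYB2-SRDX (SD, n = 3 each). The authors' deposited table gave log2 fold changes of 7.56 for LBD29 in LBD29-OE, 9.58 for MYB2 in MYB2-OE and 9.51 for MYB2 in MYB2-SRDX. MYB2 in the 3 MYB2-OE libraries was 636, 375 and 585 FPKM, lowest in replicate 2. LBD29 was also listed as higher in MYB2-OE, and that call rested on replicate 2, where it measured 109 FPKM against 1.82 and 1.93 FPKM in the other libraries of the line.

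**Figure D1:**
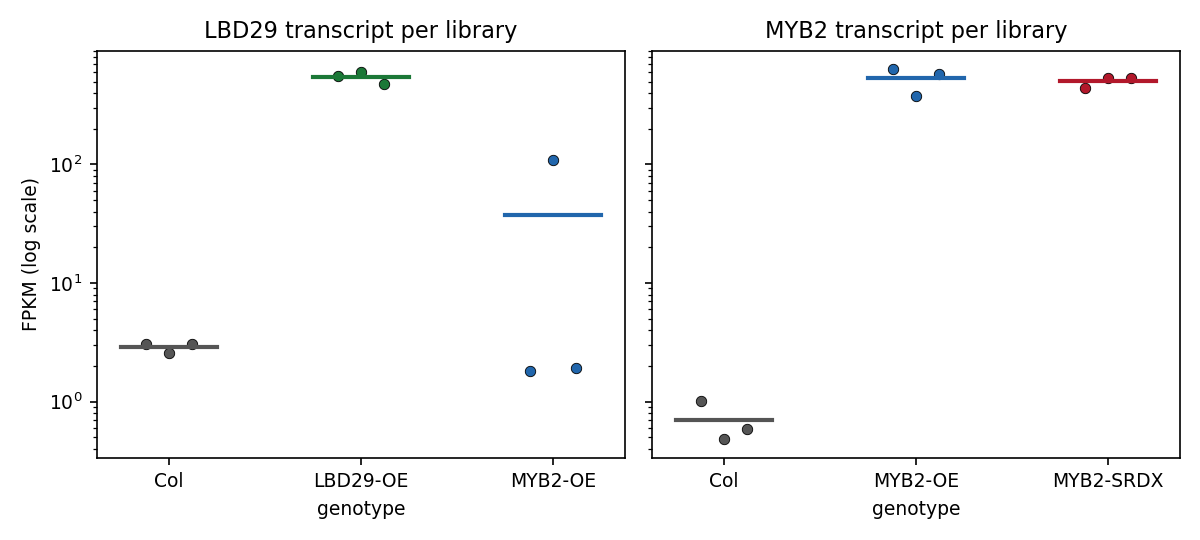
FPKM of LBD29 (left) and MYB2 (right) per library on a log axis, with 3 points per genotype and a line at their mean. LBD29 reached 546 FPKM on average in LBD29-OE and 109 FPKM in a lone MYB2-OE library, and MYB2 lay between 375 and 636 FPKM in the libraries of both MYB2 lines.

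In LBD29-OE, PGLR, CDEF1 and AIR1 were among the ranked genes most raised over Col, and IGMT4 and IGMT2 among those most lowered. Ranked genes had a symbol and a higher group mean of at least 10 FPKM. PGLR, which encodes a pectin-degrading polygalacturonase, went from 1.52 ± 0.361 to 31.6 ± 4.60 FPKM, and the cutinase gene CDEF1 from 26.8 ± 3.91 to 284 ± 47.0 FPKM (SD, n = 3). AIR1, an auxin-induced gene of root cultures, rose from 511 ± 95.2 to 4608 ± 405 FPKM (SD, n = 3). IGMT4 and IGMT2, which methylate indole glucosinolates, fell from 14.5 ± 3.44 to 0.890 ± 0.648 FPKM and from 16.2 ± 1.68 to 2.01 ± 0.695 FPKM (SD, n = 3). The iron transporter gene IRT1 fell from 162 ± 20.1 to 50.2 ± 9.27 FPKM (SD, n = 3). In all, the authors' deposited table listed 802 genes for LBD29-OE, 335 higher and 467 lower. The ubiquitin ligase gene ATL63 and the methyl esterase gene MES17 also stood among the 8 largest rises of ranked genes, at log2 fold changes of 3.11 and 2.88 in the authors' deposited table. The largest falls of ranked genes further included the purine permease gene PUP7 (-2.79), the clock-associated demethylase gene JMJD5 (-2.03), the cation exchanger gene CHX17 (-1.89), GSTF6 (-1.80) and GLP9 (-1.76) on the log2 scale of the authors' deposited table. CAB2 and RBCS2B, genes of photosynthesis, were listed as higher too, and both calls rested on LBD29-OE replicate 2, where they measured 36.4 and 32.0 FPKM against at most 0.550 and 0.320 FPKM in the other libraries of the line.

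Grouped by the fixed lists, the genes listed for LBD29-OE were few in each group. Of 21 lateral root and callus genes, 3 were higher and 0 lower, namely IAA14 (18.5 ± 1.17 to 57.6 ± 8.86 FPKM), MAKR4 (4.89 ± 0.750 to 12.01 ± 2.16 FPKM) and LBD33 (1.07 ± 0.241 to 2.24 ± 0.146 FPKM; SD, n = 3). Of 15 cell separation genes, PGLR and the abscission peptide gene IDA were higher (2 genes). IDA was low and overlapped Col, with 0.17, 0.61 and 0.66 FPKM in the line and up to 0.22 FPKM in Col. RAB18, RD29B and HAI3 were the 3 higher members among 21 abscisic acid genes, with RAB18 at 0.767 ± 0.388 FPKM in Col and 4.09 ± 2.64 FPKM in LBD29-OE (SD, n = 3). All 3 listed members of the iron deficiency list of 7 were lower, the regulator BHLH39 (17.5 ± 7.10 to 4.35 ± 1.31 FPKM) and the reductase gene FRO2 (27.7 ± 2.48 to 13.2 ± 2.24 FPKM) beside IRT1 (SD, n = 3). In the hypoxia list PCO2 and LBD41 were higher and HRE1 lower, in the nitrate list NIA1 was listed as higher and NRT2.1 as lower, and the defence genes CYP71A12 and PAD3 were both lower. HAI3, PCO2 and NRT2.1, like IDA, had group means under 1 FPKM in both Col and the line. The root hair gene PRP1 was lower, at 30.4 ± 8.89 FPKM in Col and 14.8 ± 5.40 FPKM in LBD29-OE (SD, n = 3). Among green tissue markers RBCS2B and RBCS3B were listed as higher and PORB and RBCS1A as lower, and without replicate 2 the RBCS2B and RBCS3B folds turned to log2 values of -2.25 and -2.28. Without that replicate LBD33 and HAI3 stood just under 2-fold, both at a log2 of 0.99, and HRE1 and PRP1 at -0.97 and -0.82. The NIA1 call rested on replicate 3, with 136 FPKM against 29.7 and 46.1 FPKM in the other libraries and up to 34.4 FPKM in Col, and its log2 fold was 0.65 without that replicate. RD29B, PCO2, FRO2, NRT2.1 and PAD3 also stood under 2-fold when 1 of the Col or LBD29-OE libraries was left out, at absolute log2 values of 0.84 to 0.998. RBCS1A measured 9.77, 91.0 and 10.6 FPKM in the line, so its fall deepened to a log2 of -3.41 without replicate 2. The other lists had 0 listed members.

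In MYB2-OE, HOL2, PSK2 and MYB24 rose strongly from low levels in Col, and PAD3, VSP1 and AZI1 fell. HOL2, a methyltransferase gene, went from 0.823 ± 0.342 to 68.8 ± 14.97 FPKM, and PSK2, which encodes a precursor of the growth peptide phytosulfokine, from 4.39 ± 1.74 to 174 ± 33.2 FPKM (SD, n = 3). MYB24 was listed at 0 in the 3 Col libraries and at 17.4, 7 and 9.95 FPKM in MYB2-OE. The camalexin synthesis gene PAD3 fell from 10.4 ± 0.602 to 1.39 ± 1.65 FPKM, the jasmonate-responsive storage protein gene VSP1 from 55.6 ± 7.31 to 7.97 ± 9.32 FPKM, and AZI1, a lipid transfer protein gene of systemic immunity, from 140 ± 2.54 to 22.8 ± 29.6 FPKM (SD, n = 3). The authors' deposited table listed 1271 genes for MYB2-OE, 666 higher and 605 lower. Genes were again ranked if they had a symbol and a higher group mean of at least 10 FPKM. The largest rises of ranked genes included BGLU24, ACA1, bZIP58 and GSTU4, with log2 fold changes of 4.83, 4.70, 4.203 and 4.17 in the authors' deposited table. Among the largest falls of ranked genes were the sterol desaturase gene CYP710A2 (-3.13), SP1L2 (-3.07), the purine permease gene PUP4 (-2.76), the defensin gene PDF2.1 (-2.55) and BGLU7 (-2.52) on the log2 scale of the authors' deposited table. Without replicate 2, with folds recomputed from library values, these falls were deeper, at log2 values of -4.33 for CYP710A2, -6.13 for SP1L2, -4.56 for PUP4, -2.70 for PDF2.1 and -5.90 for BGLU7, and likewise -4.30 for PAD3, -4.37 for VSP1, -4.31 for VSP2 and -4.59 for AZI1. Replicate 2 lay between Col and the other libraries for these genes, as for AZI1 with 57.0 FPKM against 5.40 and 6.02 FPKM and for VSP1 with 18.7 FPKM against 3.18 and 2.02 FPKM.

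The fixed lists had small numbers of listed members in MYB2-OE. WOX11, a regulator of root founder cells, rose from 0.320 ± 0.0889 to 3.89 ± 0.613 FPKM (SD, n = 3), and with LBD16 and PLT7 made 3 higher and 0 lower lateral root genes of 21. LBD16 rested on replicate 2, with 135 FPKM against 5.69 and 5.72 FPKM in the other libraries, and its log2 fold was 0.47 without that replicate. IDA was the 1 higher member of the cell separation list, and the auxin list held 2 lower genes, the transporter gene PIN5 (8.03 ± 1.26 to 1.76 ± 1.304 FPKM) and IAA3 (20.01 ± 2.73 to 8.46 ± 4.48 FPKM; SD, n = 3). Nitrate reductase genes NIA1 and NIA2 were both higher, at 103 ± 45.0 and 162 ± 30.2 FPKM against 24.2 ± 8.99 and 74.5 ± 8.51 FPKM in Col (SD, n = 3). The cytokinin genes ARR16 and CKX5 and the phosphate starvation genes PAP17 and PHO1;H1 were higher, 2 of 13 and 2 of 14 members. All 3 listed iron genes (BHLH101, BHLH39, IRT1) and all 3 listed defence genes (PAD3, CYP71A12, CYP79B2) were lower, as were the 2 jasmonate genes VSP1 and VSP2. Chalcone isomerase, CHI, the 1 listed flavonoid gene, fell from 132 ± 4.72 to 54.1 ± 13.0 FPKM (SD, n = 3). KIN1 was lower and RAB18 higher among abscisic acid genes, PDC2 lower and HRA1 higher among hypoxia genes, and the suberin regulator MYB41 was higher. Of the green tissue markers LHCB2.1 was higher and RBCS3B and RBCS2B lower. Without replicate 2, RAB18 and PDC2 stood under 2-fold at log2 values of 0.87 and -0.98. PLT7, HRA1 and RBCS2B were already under 2-fold in all libraries with a pseudocount of 0.1, at 0.95, 0.96 and -0.99, and RBCS2B was at -1.98 without replicate 2. Leaving out 1 library of Col or of the line also took BHLH39, IRT1, NIA2, MYB41, RBCS3B, LHCB2.1 and CYP79B2 under 2-fold. The root hair and seed lists had 0 listed members.

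In MYB2-SRDX the 3 largest falls among genes with a symbol and at least 10 FPKM were in the clock genes LHY, CCA1 and LNK2, which peak around dawn. LHY fell from 60.4 ± 3.90 to 0.537 ± 0.152 FPKM and CCA1 from 31.7 ± 2.40 to 0.347 ± 0.0577 FPKM (SD, n = 3), both being central dawn-phased repressors of the clock. LNK2, which encodes a transcriptional coactivator, fell from 25.9 ± 5.55 to 1.247 ± 0.205 FPKM and the clock activator gene RVE8 from 24.0 ± 1.33 to 3.29 ± 0.221 FPKM (SD, n = 3). Of 11 dawn-phased clock genes, a list made after these values were seen, 10 were lower and 0 higher in the authors' deposited table, the further ones being RVE1, LNK1, LNK4, PRR9, CDF1 and CDF3. No test of this count is given, because the list was made after the falls of some of its members had been seen. In each of the 10 genes every MYB2-SRDX library lay below every Col library. The evening gene ELF4 rose from 96.0 ± 25.5 to 225 ± 16.4 FPKM (SD, n = 3), and the other 9 of 10 dusk-phased genes have no value in this comparison. In MYB2-OE, RVE8 and LNK2 were higher (48.6 ± 2.26 and 70.2 ± 5.28 FPKM), as were LNK4, PRR9 and CDF1, whereas ELF4 was lower at 38.5 ± 4.85 FPKM (SD, n = 3). In LBD29-OE, ELF4, PRR5, PRR3 and FKF1 were lower (4 dusk-phased genes) and PRR9 was higher. Several of these calls lay near the 2-fold threshold: in MYB2-OE, RVE8, PRR9 and CDF1 were under it without replicate 1, and in LBD29-OE, PRR5 and PRR3 without Col replicate 3. FKF1 was under it in all libraries with a pseudocount of 0.1 (log2 of -0.99) and without LBD29-OE replicate 2 (-0.92). Col replicate 3 was the highest Col library for ELF4, PRR5, PRR3 and FKF1, as for ELF4 with 125 FPKM against 83.8 and 79.0 FPKM.

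**Figure D2:**
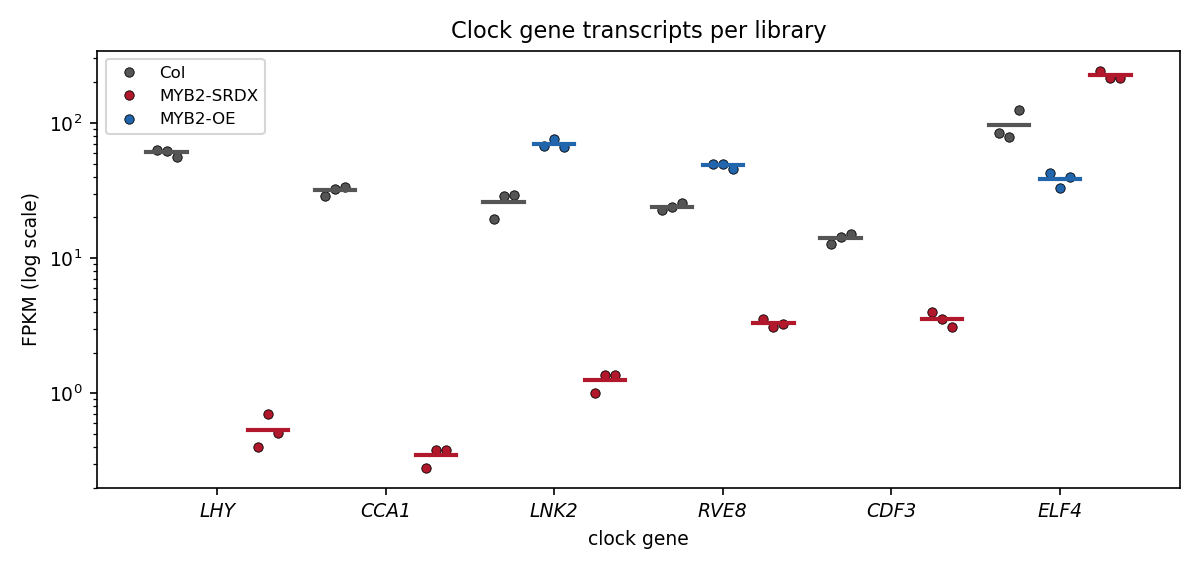
FPKM per library on a log axis for 6 clock genes in Col, MYB2-OE and MYB2-SRDX, with 3 points per genotype and a line at their mean; genotypes without points for a gene have no value in the deposited tables. LHY, CCA1, LNK2, RVE8 and CDF3 lay below Col in each MYB2-SRDX library, and ELF4 lay above.

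Rises and falls in MYB2-SRDX were likewise ranked among genes with a symbol and a higher group mean of at least 10 FPKM. The other large falls were EXLB1, an expansin-like gene (10.7 ± 3.13 to 0.853 ± 0.112 FPKM), the sulfate transporter family gene SULTR3;5 (11.9 ± 1.69 to 1.92 ± 1.11 FPKM), the small heat shock gene HSP17.4 and QQS (SD, n = 3). Rises were led by defence and detoxification genes that were high in 1 library. In the MYB2-SRDX library whose column ends in 1, the camalexin gene CYP71A12 measured 426 FPKM against 2.44 and 2.39 FPKM in the other libraries, the glutathione transferase gene GSTF6 730 against 20.2 and 30.0 FPKM, and the immune regulator gene CBP60G 52.8 against 0.680 and 0.730 FPKM. GSTU12, GSTF3 and PXMT1 were high in the same library, and without it these 6 genes had log2 folds from 0 to 0.67. NAC042 kept a fold above 2 without it, with 57.4, 5.11 and 5.08 FPKM in the 3 libraries against 1.35 ± 0.142 FPKM in Col (SD, n = 3). The authors' deposited table listed 1045 genes for MYB2-SRDX, 553 higher and 492 lower. With folds recomputed from library values, 515 of the 553 higher genes reached 2-fold over all libraries and 293 without that library, while the lower genes went from 438 to 420. By those folds its removal took the share of higher genes from 54.0% to 41.1%.

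**Figure D3:**
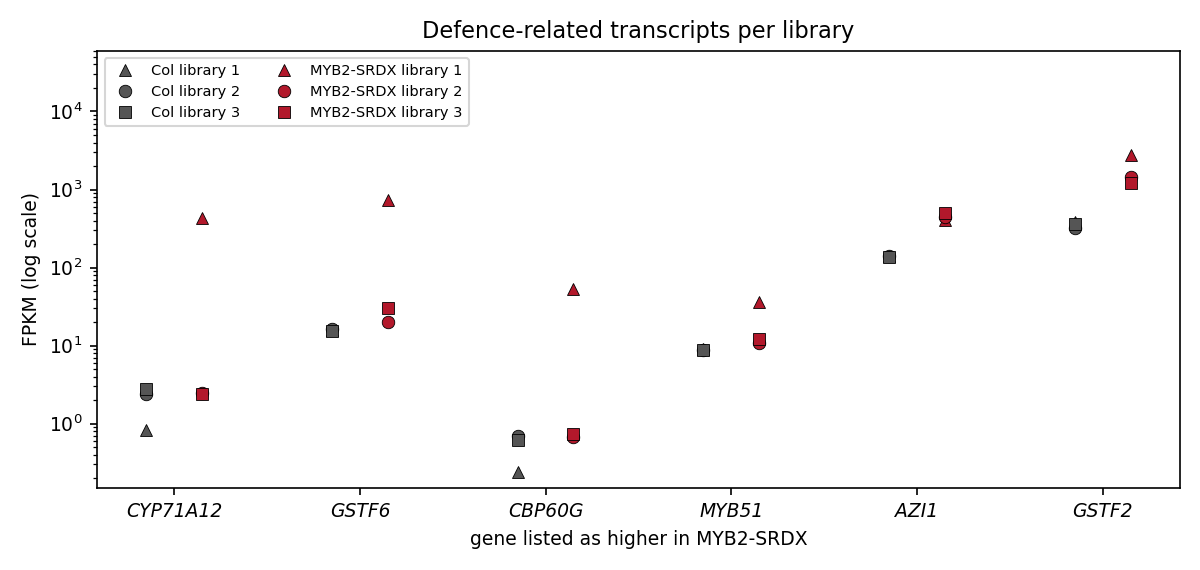
FPKM per library on a log axis for 6 genes listed as higher in MYB2-SRDX, with triangles, circles and squares for the libraries whose columns end in 1, 2 and 3. CYP71A12, GSTF6, CBP60G and MYB51 were highest in library 1. GSTF6 and MYB51, like AZI1 and GSTF2, were above Col in each MYB2-SRDX library.

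Among the fixed lists, all 5 listed defence genes of 12 were higher in MYB2-SRDX (CYP71A12, CYP71A13, FRK1, MYB51 and PAD3). Without library 1 their log2 folds were 0.26, -0.18, 0.81, 0.38 and 0.84, so all 5 stood under 2-fold, with PAD3 and FRK1 furthest above Col. All 3 PAD3 values and all 3 MYB51 values of the line lay above those of Col. MYB51 measured 36.4, 10.6 and 12.2 FPKM and PAD3 32.0, 19.5 and 17.9 FPKM in the line, against 8.76 ± 0.160 and 10.4 ± 0.602 FPKM in Col (SD, n = 3). The seed storage genes CRA1, OLEO1 and OLEO2 were listed as higher at 2.04, 0.850 and 1.09 FPKM in library 1 and at 0 in the other 2, and RBCS2B measured 9.17 FPKM there against 0.4 and 0.52 FPKM. LHCB2.1, the other listed green tissue marker, was lower (4.87 ± 0.662 to 0.503 ± 0.543 FPKM; SD, n = 3). The 4 listed abscisic acid genes of 21 were all lower (KIN2, HAI3, RD29B and CYP707A3), with KIN2 going from 192 ± 17.3 to 60.7 ± 9.36 FPKM (SD, n = 3). CYP707A3 stood under 2-fold without library 1, at a log2 of -0.86, and HAI3, RD29B and PS2 without 1 of the Col libraries. All 3 listed iron genes were lower, but IRT1 stood under 2-fold without library 1, at a log2 of -0.85. BHLH38 was at -0.998 in all libraries with a pseudocount of 0.1 and at -0.60 without library 1. FRO2 kept its fall, with 2.18, 8.01 and 8.01 FPKM against 27.7 ± 2.48 FPKM in Col (SD, n = 3). Further lower genes were LBD14 and GATA23 of the lateral root list, PHO1;H1 and PS2 of the phosphate list, where RNS1 was higher, NRT2.1 of the nitrate list and JAZ10 of the jasmonate list. Cell separation, auxin, hypoxia, cytokinin, root hair, endodermis and flavonoid lists had 0 listed members in this line.

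Across the 3 lines the direction of the fixed lists was tested by two-sided exact binomial tests of higher against lower members, with Benjamini-Hochberg adjustment over the lists of each comparison. None of the 32 list tests passed, and the smallest adjusted p was 0.291. Before adjustment 1 exact binomial p lay under 0.05, that of the abscisic acid list in MYB2-SRDX with 4 of 4 members lower (p = 0.0491). Without the libraries that stand apart 3 of them stayed lower and 0 of 29 list tests lay under 0.05 before adjustment. The xylem list (23 genes) and the cell cycle list (19 genes) had 0 members in any table. Most lists had at most 5 listed members, so these tests had little power.

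MYB2-OE and MYB2-SRDX, whose comparison the repressor fusion implies, changed shared genes mostly in opposite directions. UMAMIT17 and UMAMIT29, members of an amino acid exporter family, were higher in MYB2-OE (148 ± 15.2 and 59.4 ± 10.4 FPKM) and lower in MYB2-SRDX (6.56 ± 1.85 and 5 ± 0.832 FPKM) than in Col (28.0 ± 1.53 and 14.0 ± 1.12 FPKM; SD, n = 3). EXLB1, CYP78A8 and MRN1 followed the same course, EXLB1 with 45.4 ± 10.4, 10.7 ± 3.13 and 0.853 ± 0.112 FPKM in MYB2-OE, Col and MYB2-SRDX (SD, n = 3). In the other sense, the glycine-rich protein gene GRP3S measured 6.77 ± 3.14, 33.1 ± 5.02 and 279 ± 98.0 FPKM, the glutathione transferase gene GSTF2 74.5 ± 12.8, 351 ± 29.4 and 1820 ± 856 FPKM, and AZI1 22.8 ± 29.6, 140 ± 2.54 and 453 ± 47.6 FPKM in MYB2-OE, Col and MYB2-SRDX (SD, n = 3). GLP9 and IGMT4 were also lower in MYB2-OE and higher in MYB2-SRDX. SWEET12 and TCH3, besides MYB2 itself, were higher in both lines, and the anion channel family gene SLAH1, CYP82C4, SP1L2, IRT1 and the potassium channel gene SKOR were lower in both. In MYB2-SRDX the TCH3 call rested on library 1 (36.1 FPKM against 5.39 and 11.9 FPKM, with 8.77 ± 0.540 FPKM in Col; SD, n = 3). SKOR and IRT1 were lowest in that library, at 2.78 and 13.4 FPKM, and stood under 2-fold without it.

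The tables shared 299 genes, and 210 of them (70.2%, exact binomial 95% interval 64.7 to 75.4%) lay in opposite directions. They comprised 112 genes higher in MYB2-OE and lower in MYB2-SRDX and 98 with the reverse, beside 44 higher and 45 lower in both. By folds recomputed from library values these classes held 98, 83, 35 and 39 genes, and without MYB2-OE replicate 2 and MYB2-SRDX library 1 they held 95, 62, 23 and 33, with 73.7% of 213 genes opposite. Independent directions would have put 49.9% in the same direction, where 29.8% was observed (two-sided Fisher's exact test, p = 2.23e-12). Genes are not independent replicates, so this p-value and the interval overstate the certainty. Independent lists drawn from 27550 protein-coding genes, an approximation of what could have been listed, would share 11.9, 12.1, 13.4 and 10.8 genes in these 4 classes, in the order given. Unchanged lines simulated against the shared Col libraries gave 90.7% of genes in the same direction among 19.4 genes past 2-fold in both, so shared controls alone push towards the same direction. Among the 48 genes past a log2 of 2 in both tables, 24 (50%) were opposite, so the excess of opposite genes was not seen at that threshold. That threshold had no FPKM floor, and folds of low genes are the least certain. Of 70 shared genes with a higher group mean of at least 10 FPKM in each comparison, 54 (77.1%) were opposite.

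**Figure D4:**
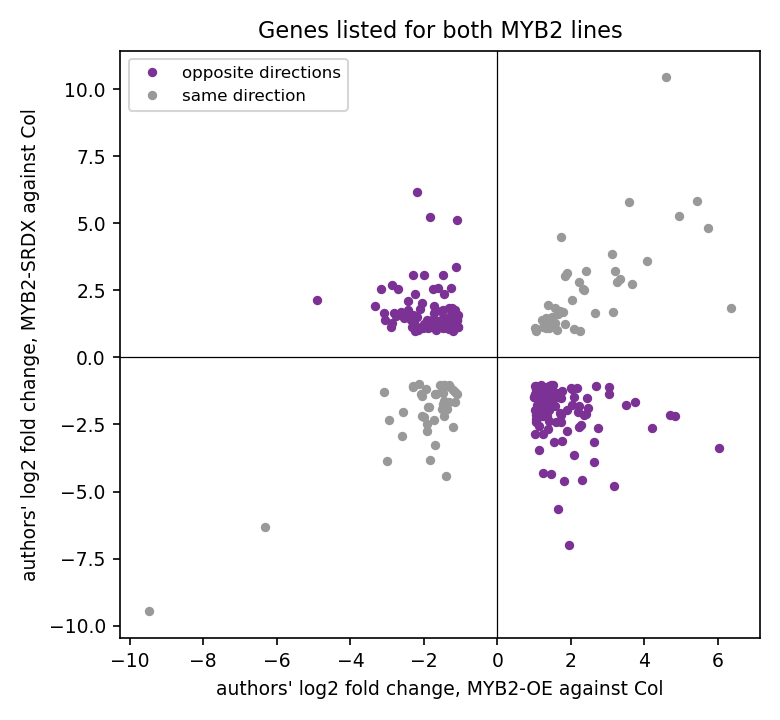
Authors' log2 fold changes of the genes listed in both MYB2 tables, MYB2-OE on the horizontal and MYB2-SRDX on the vertical axis, with 1 point per gene and MYB2 itself left out. Opposite directions (purple, 210 genes) fill the upper left and lower right; the extreme points include genes listed at 0 in a group.

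LBD29-OE and MYB2-OE shared genes that mostly moved the same way, which bears on the series' question of targets downstream of both factors. QQS rose from 12.2 ± 2.76 FPKM in Col to 44.9 ± 3.52 FPKM in LBD29-OE and 32.4 ± 5.93 FPKM in MYB2-OE, and BT2 from 35.7 ± 7.39 to 97.0 ± 35.3 and 77.8 ± 19.9 FPKM (SD, n = 3). JMJD5 fell from 20.2 ± 6.95 to 4.98 ± 0.274 and 5.47 ± 0.574 FPKM, and the abscisic acid receptor gene PYL6 from 21.0 ± 4.61 to 6.21 ± 0.898 and 7.01 ± 1.43 FPKM (SD, n = 3). IGMT4, GLP9 and PDF2.1 were lower and NIA1 higher in both. LBD29 and CDEF1 were listed as higher in both, but in MYB2-OE they rested on replicate 2, where CDEF1 measured 196 FPKM against 28.8 and 34.0 FPKM. BT2 also stood just under 2-fold in MYB2-OE without that replicate, and the NIA1 call in LBD29-OE rested on replicate 3 of that line (136 FPKM against 29.7 and 46.1 FPKM). OSM34, an osmotin-like gene, went against the trend, with 18.7 ± 5.205 FPKM in LBD29-OE, 49.3 ± 11.2 FPKM in Col and 347 ± 123 FPKM in MYB2-OE (SD, n = 3). Of 283 shared genes 245 (86.6%, exact binomial 95% interval 82.0 to 90.3%) moved the same way, 86 higher and 159 lower, where independent directions would give 53.2% (two-sided Fisher's exact test, p = 1.05e-35). Genes are not independent replicates and the Col libraries were shared, so this p-value and the interval overstate the certainty. Independent lists would share 8.10 higher and 10.3 lower genes, and 7.36 and 11.3 in the opposite classes, where 11 and 27 were observed. The 11 genes were higher in LBD29-OE and lower in MYB2-OE, and the 27 the reverse. By recomputed folds the classes of 86, 159, 11 and 27 genes held 70, 131, 9 and 23. With replicate 2 of both lines left out they held 61, 134, 3 and 25, and 87.4% of 223 genes moved the same way. Simulated unchanged lines gave 88.9% in the same direction among 20.5 genes past 2-fold in both. The observed genes were chosen by their calls and the simulated lines were not, so neither the direction shares nor the numbers of genes can be compared. The direction share alone therefore cannot separate shared effects from shared controls. Over the 1228 genes of the MYB2-OE table with a log2 value for LBD29-OE, the covariance of the log2 values was 1.22 against 0.0807 in the simulation, a difference of 1.14. These genes were chosen by their MYB2-OE call, which the simulation did not copy. The difference therefore cannot separate shared effects from shared controls, and LBD29 and replicate 2 stayed in. The correlation of these log2 values across genes, which are not independent replicates, was 0.456.

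LBD29-OE and MYB2-SRDX shared 227 genes, most of them with opposite directions. The chaperone gene HSP90.1 measured 92.6 ± 8.94 FPKM in LBD29-OE, 35.3 ± 13.7 FPKM in Col and 12.9 ± 1.64 FPKM in MYB2-SRDX, and its cochaperone gene Hop3 31.5 ± 5.64, 15.3 ± 2.86 and 6.54 ± 2.90 FPKM (SD, n = 3). HSP70 and QQS took the same course, and IGMT2, IGMT3, IGMT4, GSTF6 and GLP9 the reverse, IGMT3 with 38.4 ± 9.05, 117 ± 13.5 and 316 ± 173 FPKM (SD, n = 3). The HSP70 libraries of MYB2-SRDX (41.9 ± 12.8 FPKM) overlapped those of Col (92.1 ± 46.5 FPKM; SD, n = 3). In MYB2-SRDX the rises of GSTF6, IGMT2 and IGMT3 were under 2-fold without library 1, where IGMT2 measured 184 FPKM against 21.2 and 23.3 FPKM, and Hop3 was under 2-fold in either line without its library that stands apart. IRT1, FRO2, SLAH1 and CYP82C4 were lower in both, IRT1 under 2-fold in MYB2-SRDX without library 1. Opposite directions held for 146 of the 227 genes (64.3%, exact binomial 95% interval 57.7 to 70.5%). They comprised 112 genes lower in LBD29-OE and higher in MYB2-SRDX and 34 the reverse, beside 28 higher and 53 lower in both. Independent directions would have put 44.7% in the same direction, where 35.7% was observed (two-sided Fisher's exact test, p = 0.00217). Genes are not independent replicates, so this p-value and the interval overstate the certainty. Independent lists would share 9.37, 5.98, 6.72 and 8.34 genes in these classes, in the order given, and the simulated unchanged lines gave 89.1% in the same direction among 18.5 genes. The covariance over 997 genes of the MYB2-SRDX table was -0.211 against 0.0937 in the simulation, a difference of -0.305, with a correlation of -0.0740 across genes, which are not independent replicates. These genes were chosen by their MYB2-SRDX call, which the simulation did not copy, so the difference cannot separate shared effects from that choice. Without LBD29-OE replicate 2 and MYB2-SRDX library 1, 146 genes were shared and 83 of them (56.8%, exact binomial 95% interval 48.4 to 65.0%) were opposite (two-sided Fisher's exact test, p = 0.0778). Genes lower in LBD29-OE and higher in MYB2-SRDX numbered 100 by recomputed folds and 54 without these libraries, and the reverse class 32 and 29. Of the 39 genes past a log2 of 2 in both comparisons, without an FPKM floor, 48.7% were opposite. Of 41 shared genes with a higher group mean of at least 10 FPKM in each comparison, 70.7% were. With 3 Col libraries the controls could not be split, so part of the excess over independent lists in the same-direction classes may come from the shared controls.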

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

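The tests in this part were chosen after the results were seen. The direct comparison of the MYB2 lines was run because MYB2-OE and MYB2-SRDX shared many genes with opposite calls. Among the 299 genes listed for both lines, limma with Benjamini-Hochberg adjustment on log2(FPKM + 1) found 177 that differed between the lines, 103 higher and 74 lower in MYB2-OE. These were 173 of the 210 genes with opposite calls and 4 of the 89 with calls in the same direction. Genes over 2-fold apart from Col in opposite directions differ between the lines by construction, so the contrast restates the opposite calls and is no independent evidence of them. For 170 of the 210 genes with opposite calls, each library of both lines lay outside the range of the Col libraries, on opposite sides, a difference that was not tested as such. UMAMIT17, UMAMIT29, EXLB1, GRP3S, GSTF2 and AZI1 are examples of opposite calls. The genes entered this comparison because both tables listed them, so the counts describe the listed genes and not the transcriptome.

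Whether chance assignment of libraries to groups gives as many genes was counted over the 10 splits of the 6 libraries of each comparison. In each comparison 1 split, the real one, reached its own number of genes past limma. The real numbers were 296 in LBD29-OE, 626 in MYB2-OE and 310 in MYB2-SRDX, and the highest number in another split was 1, 5 and 0. The genes entered because they differ in the real grouping, so this selection fixed the outcome and the count says nothing about chance. With 10 splits the share also cannot go under 0.1, which is too few for a decision at 0.05.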

How the results depend on the processing

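Limma on listed genes, folds with a pseudocount of 0.1, also with replicates left out, the direct comparison and the joint removal of libraries that stand apart were chosen after the data were seen; the pseudocount, replicate and block settings of limma were fixed earlier. Every call kept its place under Q thresholds of 0.01 and 0.001 and without a fold threshold, which the construction of the tables guarantees. In LBD29-OE, MYB2-OE and MYB2-SRDX, 224, 390 and 357 genes reached a log2 of 2, 226, 439 and 273 a mean of 10 FPKM, and 312, 634 and 429 a 2-fold change with a pseudocount of 1; the last fall follows from shrunken folds of low genes. Without each replicate in turn, and with a pseudocount of 0.1, the counts ranged from 616 to 722, 1008 to 1180 and 713 to 942.

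Limma on the listed genes gave 296, 626 and 310 past log2 1 with a pseudocount of 1, 669, 1206 and 649 with no fold threshold, and 632, 1124 and 649 with a pseudocount of 0.1. Leaving out replicates gave 243 to 305, 534 to 720 and 245 to 337, and 171 to 185 for the direct comparison of the MYB2 lines. With the replicate number as a block, 286 and 629 genes passed in LBD29-OE and MYB2-OE (595 and 1216 with no fold threshold). Same-numbered libraries correlated at -0.0860 to 0.0210 with LBD29-OE and 0.0114 to 0.0194 with MYB2-OE, where each library correlated best with its own number, so the numbers were not taken to pair samples. The block was not run for MYB2-SRDX, alone or against MYB2-OE, because the digits that end its column names could not be matched to sample titles.

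Opposite genes of the MYB2 lines numbered 24 (50%) at a log2 of 2, 54 (77.1%) at 10 FPKM, and 77.4% were opposite among genes past limma. LBD29-OE and MYB2-OE shared 45 genes at a log2 of 2 and 60 at 10 FPKM (91.7% the same direction). LBD29-OE and MYB2-SRDX shared 39 at a log2 of 2 (48.7% opposite, below an even split), 41 at 10 FPKM (70.7%), 122 past limma and 146 (56.8%) without the libraries that stand apart. The cause was not tested. No gene list passed in 24 tests at 10 FPKM or 29 without those libraries.

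The counts in this paragraph leave out genes named in a comparison only for an overlap. Of the other 41, 50 and 46 named genes in LBD29-OE, MYB2-OE and MYB2-SRDX, 33, 45 and 29 kept a 2-fold change without the library that stands apart. Of these counted genes, those reversing were RBCS2B (-2.25) and RBCS3B (-2.28) in LBD29-OE, LBD29 (-0.60) in MYB2-OE, and RBCS2B (-1.30), OLEO2 (-0.42) and CYP71A13 (-0.18) in MYB2-SRDX, since their rise stood in that library. With a pseudocount of 1, 29, 38 and 30 kept it, and 40, 47 and 45 with 0.1. Without each of the 6 libraries of a comparison in turn, 25, 33 and 26 of these counted genes kept it every time. DESeq2, the read filter and a fit of all 4 groups were not run, because they need counts or all genes.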

Other observations

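Apart from the test on dusk-phased clock genes, the tests in this part were chosen only after the result was seen. Gene ontology terms set the higher against the lower genes of each table by Fisher's exact test with Benjamini-Hochberg adjustment. In LBD29-OE 37 of 439 terms passed. Response to heat held 15 higher and 4 lower genes (adjusted p = 0.0178), extracellular region 64 and 47 (adjusted p = 0.00607) and methyltransferase activity 0 and 11 (adjusted p = 0.0458). Without replicate 2 of that line, photosynthesis held 0 higher and 15 lower genes (adjusted p = 0.0170). In MYB2-OE 7 of 616 terms passed, among them defense response with 29 higher and 58 lower genes (adjusted p = 0.0425), a term that was not among the 5 of 583 that passed without replicate 2. In MYB2-SRDX 33 of 579 terms passed, with defense response at 63 higher and 24 lower (adjusted p = 0.00402), cellular response to hypoxia at 18 and 0 (adjusted p = 0.00167), anion transport at 5 and 24 (adjusted p = 0.00462) and circadian rhythm at 2 and 13 (adjusted p = 0.0497). Without library 1 of MYB2-SRDX, 3 of 447 terms passed, all of transport: nitrogen compound transport at 0 and 19, anion transport at 1 and 23, and anion transmembrane transporter activity at 1 and 22 (adjusted p = 0.0314, 0.0314 and 0.0386).

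Transcription factor families were counted without a test. Of MYB family genes 21 were higher and 3 lower in MYB2-OE, 7 and 1 in LBD29-OE, and 8 and 10 in MYB2-SRDX, with MYB2 itself among the higher genes of both MYB2 lines. AP2-EREBP genes were 1 higher and 12 lower in LBD29-OE. Of the 115 genes in all 3 tables, 57 were lower in both overexpression lines and higher in MYB2-SRDX, 17 were lower in all 3, 14 higher in all 3 and 12 higher in both overexpression lines and lower in MYB2-SRDX. In the authors' deposited table the median LBD29-OE log2 was 0.27 for the genes higher and -0.47 for those lower in MYB2-OE. It was -0.46 for the genes higher and -0.05 for those lower in MYB2-SRDX, of which 53.3% were below 0, so the latter showed no clear opposite direction.

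MYB2-OE replicate 2 lay between Col and the other MYB2-OE libraries for 115 of 115 strongly changed genes, by a median of 0.355 of the way to Col (quartiles 0.294 and 0.429), against -0.202 and -0.103 for the other libraries of the line, taken in the same way over 60 and 65 genes. LBD29-OE RNA alone as an admixture is argued against by 1 of the 3 genes that stood over 4-fold above each Col and other MYB2-OE library: LBD16 (135 FPKM) had a log2 of -0.20 in LBD29-OE in the authors' deposited table, unlike CDEF1 and LBD29, so this rests on 1 gene. RNA of other plants mixed into replicate 2 is consistent with the shares of risen and fallen genes, 0.393 and 0.333, whose difference of 0.0609 lay under the bound of 0.1. Weaker MYB2 transgene expression (MYB2 itself lay 0.386 of the way) would keep values between Col and the line; the test of such high genes gave 3, at its bound, and an earlier form gave LBD29 at 35.4 times the next highest library. Both forms restate values that had prompted the question, so neither is an independent test. LBD29, LBD16 and CDEF1 in replicate 2 did lie outside the range of Col and the other MYB2-OE libraries. Weaker MYB2 expression alone therefore leaves these 3 genes of 1 library unexplained. For the 115 genes it cannot be told apart from admixture, and no biological explanation from the design was tested.

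In MYB2-SRDX library 1, 117 listed genes, with CYP71A12, GSTF6 and CBP60G among them, lay over 4-fold above both other libraries of the line (median log2 change over Col 4.09 against -0.0498). Choosing genes this way favoured low values in the other 2 libraries but left room for a log2 of 1 or more over Col in 83 genes, of which 8 reached it (median 0, quartiles -0.365 and 0.483), which argues against an effect of the MYB2-SRDX genotype shared by its 3 libraries for most of the 83. For the remaining genes the median of -0.457 follows from the choice and decides nothing. Tissue of another kind in that library stays open: 4 of the 5 listed green tissue and seed markers lay over 4-fold above both other libraries, but at 0.850 to 9.17 FPKM, and LHCB2.1 there (1.13 FPKM) was below its Col mean of 4.87 FPKM, and the markers entered only because they were listed, so the test cannot decide. A defence reaction of those plants may also underlie the pattern and was not tested.

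Dawn-phased clock genes were lower in MYB2-SRDX, 10 of 11, with a median log2 of -2.18, while MYB2-OE listed 5 of them as higher. The explanation of 1 unusual MYB2-SRDX library is argued against, since the median was -2.23 without library 1, a shift of 0.0535. A shift in circadian phase or clock state of the harvested roots predicted at least 3 dusk-phased genes listed as higher, and 1 (ELF4) was. That bound was wrong by design, because 9 of the 10 dusk-phased genes have no value in a table of called genes, so such a shift, for example from another time of harvest, cannot be told apart from an effect of the MYB2-SRDX fusion. Harvest times are not given in the sources used here, and an effect of the fusion on the clock may be followed up as a hypothesis.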
